A study of Caenorhabditis elegans with 4 samples.

How the data were processed

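Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to the JUN-1 protein in L1 larvae, the first larval stage of the nematode Caenorhabditis elegans. JUN-1 is the worm relative of mammalian c-Jun, a basic leucine zipper transcription factor. Hermaphrodites of strain OP234 carried an integrated transgene, wgIs234, that makes JUN-1 fused to GFP. Per the labels' protocols, worms were grown at 20 degrees Celsius on bacterial plates, fixed with 2% formaldehyde and quenched in 100 mM Tris. The stage label carries a further entry that looks like another temperature, and which of the values applied was not settled here. Chromatin was sonicated, 10% was kept as input DNA, and the rest was precipitated with a polyclonal goat antibody against GFP. The series holds 4 libraries, which are ChIP replicates 1 and 2 and input replicates 1 and 2.

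The values analysed were 3 lists of peaks, 1 for each ChIP replicate and 1 named combined. Per the file headers and the source column of each list, the authors called peaks with PeakSeq on genome build WormBase WS180. Each deposited peak has a chromosome, a start, an end and 1 q-value, the authors' own value for that peak. The q-value stands in a score column and is repeated as an attribute, and both were equal in all 4277, 2370 and 4272 peaks of the combined, replicate 1 and replicate 2 lists. The PeakSeq version, the aligner, the read filters, the thresholds, the use of the input libraries and the way the combined list was made are not given in the sources used here. The inputs have no list of their own and entered no comparison here. No list holds read counts, so sequencing depth is unknown, and the q-values depend on it. Ranks and -log10 q were used within a list, and -log10 q was set side by side between the replicate lists only at shared peaks.

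Peaks were ranked by q within each list. Peaks were called shared when they overlapped by at least 1 bp. The overlap between replicates was compared with 9999 random placements of the replicate 2 peaks, with widths kept and within each chromosome. The smallest two-sided p these placements can give is 0.0002. Spearman and Pearson correlations at peaks overlapping one to one were tested with 100000 permutations. Shares of peaks per chromosome and in chromosome centres were tested with two-sided exact binomial tests. The 25 strongest peaks were compared with the rest by Fisher's exact test. Values were adjusted by the Benjamini-Hochberg method over the 6 chromosomes. Intervals of shares are exact Clopper-Pearson intervals at 95%, and they cover counting error only. Intervals of median ratios come from 2000 bootstrap resamples of peaks. The recovery of replicate 2 peaks in replicate 1 was compared between chromosomes within 10 strata of q rank, by permutation. All p-values are over peaks or placements, never over replicates. Peaks are not independent of each other, so these p-values are smaller than independent observations would give. Nothing in the labels says that the replicates came from separate cultures.

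The gene table used here belongs to assembly WBcel235, which differs from the build of the lists, and coordinates were not converted. For this reason 5 planned results were not analysed here, namely peaks at promoters, AP-1 sequence motifs in peaks, enrichment of 28 gene lists, peaks at tRNA genes and peaks around the source of the transgene. For the same reason the rule for named items kept only its part without genes. It takes the 25 strongest combined peaks that overlap a peak in both replicates, and these are given by WS180 position without gene, exon or intron. Chromosome lengths of WS180 were not used here. Each chromosome was taken to run from the first to the last peak over the 3 lists. The first peak on X began at position 324043, and on every autosome at 51159 or before. The span may thus leave out more of X than of the autosomes, which would make the reference share of X too small. The plan foresaw only counts for X without chromosome lengths, so the test against this span was chosen after the data were seen.

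Results were recomputed under other choices where these applied. Overlaps were also counted with a reciprocal overlap of 50% or, except for the rank correlation, with midpoints within 200 bp. Shares per chromosome and in centres were also taken from stronger peaks only and from each replicate's list in place of the combined list. The closing section names the other choices. The scripts were tested on simulated data. A simulated overlap of 88.8% was found as 88.2%, and 2 of 40 unrelated simulated lists were called. A chromosome I recovery set to 30% was found as 31.0%, and 6 of 100 permuted chromosome labellings were called. The unrelated lists and the labellings were drawn by the same random models that the tests assume. These call rates therefore check the computation only, and not false calls with peaks that lie unevenly. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.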

Results

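JUN-1::GFP ChIP-seq in L1 larvae was described by 3 peak lists. The list of ChIP replicate 1 held 2370 peaks, that of ChIP replicate 2 held 4272, and the combined list held 4277. Median peak width was 358 bp in replicate 1, 352 bp in replicate 2 and 352 bp in the combined list. The peaks covered 1041475 bp in replicate 1 and 1848948 bp in replicate 2. The largest q-value was 0.000273 in replicate 1 and 0.000383 in replicate 2. Read depth was unknown for all libraries.

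The strongest JUN-1::GFP peaks lay on the X chromosome. The first 11 combined peaks, ranked by the authors' q-value, were all on X, as were the first 11 of replicate 2 and 10 of the first 11 of replicate 1. Among the 25 strongest combined peaks 16 were on X, a share of 64% (95% exact interval 42.5 to 82.0), against 17.8% of the remaining peaks. The odds ratio was 8.21 (Fisher's exact test, two-sided, p = 4.5e-07, adjusted p = 2.7e-06 over 6 chromosomes). In replicate 1 the count was 18 of 25 (Fisher's exact test, adjusted p = 4.2e-08) and in replicate 2 it was 16 of 25 (Fisher's exact test, adjusted p = 2.9e-06). Of the 25 combined peaks, 21 had the same start and end as a replicate 2 peak. The replicate 2 count therefore repeats the combined one and is no separate support. Chromosome V, which held more peaks than any other chromosome, had 4 of the 25 strongest combined peaks (Fisher's exact test, adjusted p = 0.26). This comparison was chosen after the data were seen. A precipitation from worms without the tag was not analysed here, so whether JUN-1 itself was bound at these peaks was not tested.

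The strongest combined peak was X:8035839-8036953, 1115 bp wide, with q = 4.6e-245, and q = 4.7e-167 in replicate 1. It had the same start and end in all 3 lists. The next were X:6296027-6297002 with a combined q of 2.5e-210, X:2996311-2997559 with 1.3e-206 and X:16929304-16931893 with 3.2e-204. In replicate 1 these 3 peaks ranked 3, 4 and 9. The following combined peaks were X:11093675-11094599, X:14525280-14526430, X:4208373-4209745, X:13700390-13701160 and X:12362617-12363668, with q from 1.9e-195 to 1.0e-174. X:9465376-9466239 and X:16056059-16056878 completed the run on X. The other X peaks among the 25 were X:11937013-11937862, X:1626754-1627572, X:1453792-1454922, X:1344654-1345408 and X:16681628-16682365, with q from 4.1e-129 to 5.5e-95.

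The strongest autosomal peak was IV:14032434-14034702, combined rank 12, with q = 1.6e-139. Chromosome V followed with V:9730812-9732313 at 1.3e-125 and V:9342897-9344609 at 5.2e-121, and with V:7727779-7730988 and V:1151129-1152090 at ranks 23 and 25. The others were III:4281479-4282710, I:4171897-4172644, II:5543277-5544434 and I:7079133-7084137. Of the 25 peaks, 21 ranked among the 25 strongest of replicate 1 and 23 among its 50 strongest. The exceptions beyond rank 50 were V:7727779-7730988, at rank 67, and I:7079133-7084137, at rank 123, and each of these covered 2 replicate 1 peaks.

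The share of X fell with peak rank. Combined peaks of ranks 51 to 100 lay on X in 32.0% of cases (95% exact interval 19.5 to 46.7), the 100 peaks after rank 100 in 14% (7.87 to 22.4) and those from rank 1601 on in 18% (16.6 to 19.5). In replicate 1 the share at ranks 51 to 100 was lower, 20% (10.0 to 33.7). Over the whole combined list X held 773 of 4277 peaks, or 18.1% (16.9 to 19.3), and it made up 17.3% of the covered length. This difference did not pass the threshold (exact binomial test, two-sided, p = 0.157). The higher share of X was seen in the strongest peaks, and this test against covered length did not detect it in the list as a whole. The test includes chromosome V, whose many peaks lower the share of every other chromosome. Over the whole combined list X had 45.1 peaks per Mb, fewer than V. Chromosomes I, II, III and IV had 28.4 to 39.4, and the difference of X from them was not tested. With peaks closer than 5000 bp counted as 1 cluster the share of X was 18.8% (exact binomial p = 0.033).

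**Figure D1:**
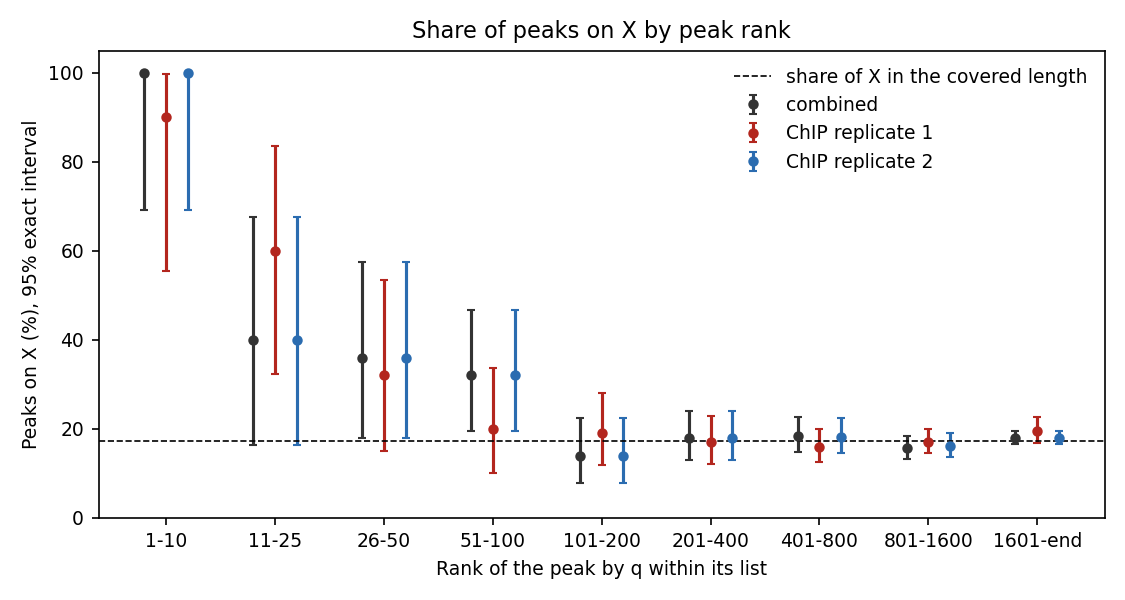
Share of peaks on chromosome X, in percent, by rank of the peak within its list, for the combined list and both ChIP replicates. Points are shares, bars are 95% exact intervals and the dashed line is the share of X in the covered length, 17.3%; the 10 strongest combined peaks were all on X, and from rank 1601 on the combined share was 18%.

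Among the chromosomes, V carried the most peaks per Mb. It held 1400 combined peaks, 67 per Mb, or 32.7% of peaks (95% exact interval 31.3 to 34.2) on 21% of the covered length. This was 1.56 times the share of length (exact binomial test, two-sided, adjusted p = 3.5e-70). With peaks closer than 5000 bp counted as 1 cluster the share of V was lower, 26.2% (exact binomial p = 5.5e-11). Chromosome X had 45.1 peaks per Mb, III 39.4, I 38.1, IV 32.0 and II 28.4. The combined shares of II and IV were 0.66 and 0.74 times their shares of length (exact binomial test, adjusted p = 8.3e-23 and 3.5e-15). Those of I and III were 0.89 and 0.92 times (exact binomial test, adjusted p = 0.0023 and 0.036). The excess on V lowers the shares of all other chromosomes, so these ratios alone do not show depletion. In replicate 1 the share of V was 33.5% (exact binomial test, adjusted p = 4.7e-44), and that of I was 9.16%, below the 13.4% in replicate 2. All tests of a chromosome's share of peaks against its share of the covered length, that of X included, were chosen after the data were seen.

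Autosomal peaks were concentrated in chromosome centres, and X peaks were not. C. elegans autosomes have arms and centres that differ in gene content, which is why they were compared. Of 3504 autosomal combined peaks, 2163 lay in the central 50% of the span of their chromosome, a share of 61.7% (95% exact interval 60.1 to 63.3; exact binomial test, two-sided, p = 3.9e-44). The share was 65.6% on V, 61.1% on I, 60.3% on II, 58.8% on IV and 56.5% on III, and each passed the threshold (exact binomial tests, largest adjusted p = 0.0036). On X it was 49.4% (45.8 to 53.0; exact binomial p = 0.77). The difference between autosomes and X, tested after the data were seen, gave an odds ratio of 1.65 (Fisher's exact test, p = 4.1e-10). In replicate 1 the autosomal share was 60.8% and that of X was 46.5% (Fisher's exact test, p = 5.9e-08). Within replicate 1, III and IV each gave 55% and did not pass the threshold (exact binomial tests, adjusted p = 0.093).

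The window of 1 Mb with the most combined peaks was V:11000001-12000000, with 107. The densest windows on other chromosomes were I:9000001-10000000 with 73, III:5000001-6000000 and X:13000001-14000000 with 59 each, IV:8000001-9000000 with 53 and II:5000001-6000000 with 47. The sparsest inner windows were II:3000001-4000000 with 10 and IV:15000001-16000000 with 11.

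**Figure D2:**
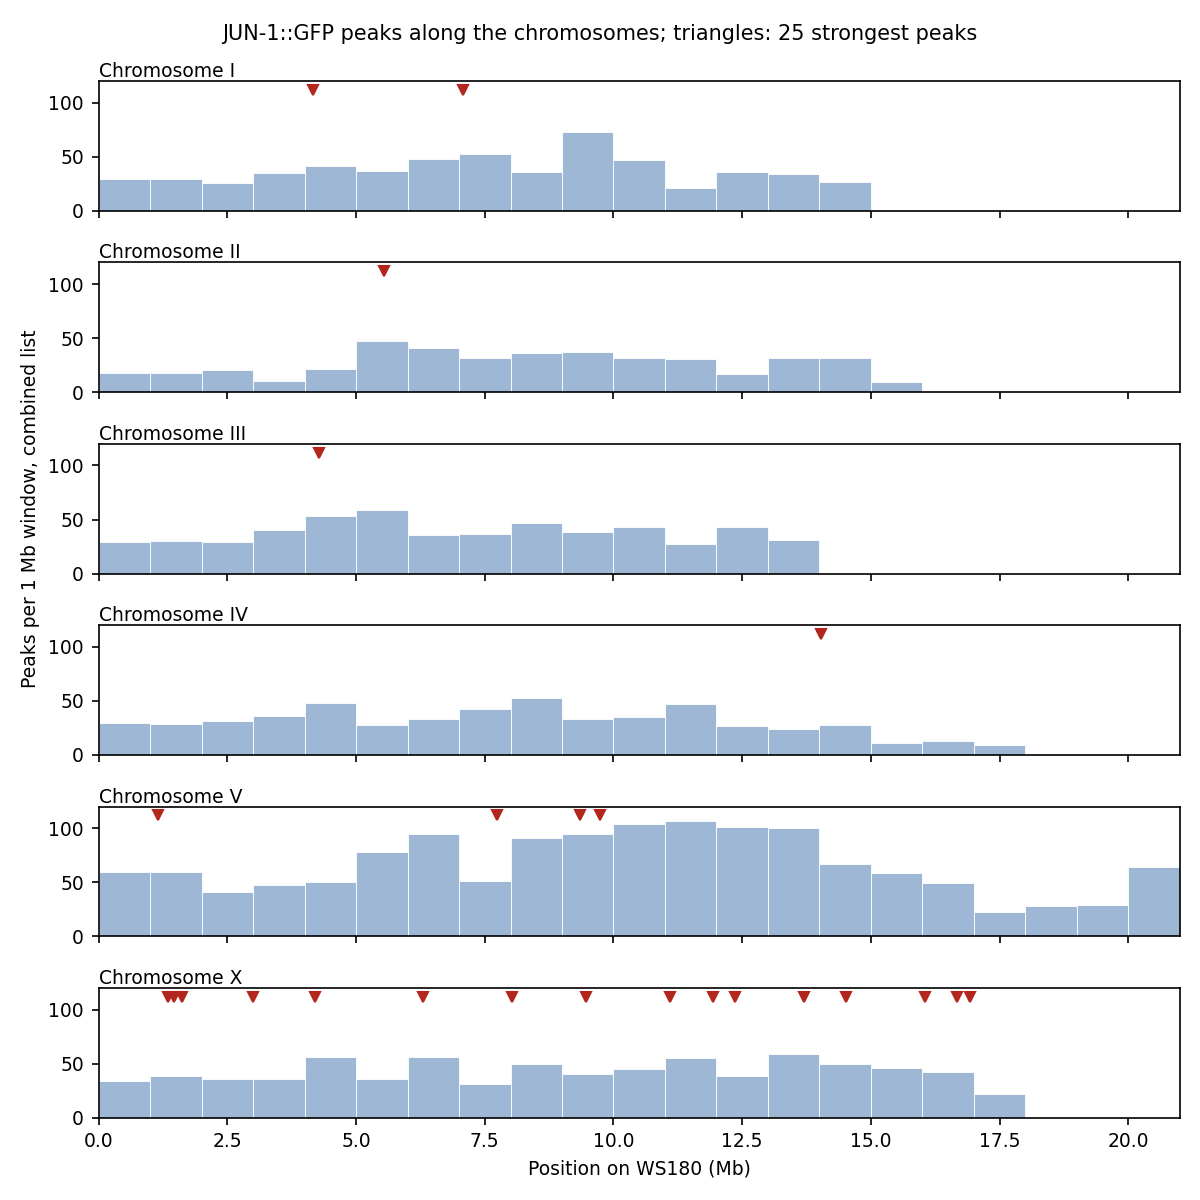
Number of combined peaks per window of 1 Mb along the 6 chromosomes, at WS180 positions in Mb, with red triangles at the 25 strongest peaks found in both replicates. Bars reach 107 on V, and 16 of the 25 triangles lie on X.

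The ChIP replicates were compared to ask which peaks were found again. Nearly all replicate 1 peaks had a counterpart: 2357 of 2370 overlapped a replicate 2 peak, or 99.5% (95% exact interval 99.1 to 99.7). Random placement gave 91.0 on average, or 3.84%, and at most 127 (permutation p = 0.0002, the smallest the placements can give). Placement was uniform within each chromosome, so this test cannot tell JUN-1 binding in both replicates from background that both share. In the other direction 2324 of 4272 replicate 2 peaks were found in replicate 1, or 54.4% (52.9 to 55.9). Recovery followed peak strength. All of the 100 strongest replicate 2 peaks were found, 99.8% of the 400 after rank 100, 79.4% of ranks 1501 to 2000 and 6.13% of ranks 3001 to 4272. The replicate lists were not copies of each other, since 23 peaks had equal start and end and 0 of them had equal q. The lists do not show whether that of replicate 2 was called without reads of replicate 1, since the combined list was nearly identical to it.

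Peak strength was closely ranked alike in both replicates. At 2283 peaks overlapping one to one, -log10 q had a Spearman rho of 0.91 and a Pearson r of 0.98 (permutation p = 1e-05 for each, the smallest possible, and adjusted p = 1e-05 over 8 correlations). Peak width had a rho of 0.88. These are correlations across peaks, which are not independent replicates. If reads of replicate 1 also entered the replicate 2 list, the correlations would come in part from shared reads. The value of -log10 q was lower in replicate 1 at nearly all shared peaks, and its median ratio to replicate 2 was 0.62 outside chromosome I.

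Peaks on chromosome I were found again in replicate 1 less often than peaks elsewhere. Of 571 replicate 2 peaks on I, 216 were found, or 37.8% (95% exact interval 33.8 to 41.9), against 56.5% expected from the other chromosomes at equal q rank (permutation p = 0.0002, the smallest possible, adjusted p = 0.0004). Chromosomes II, III and IV lay above their expectations, which include the low recovery on I. Recovery was 55.6% on II against 49.8% expected, 60.7% on III against 52.7% and 60.7% on IV against 54.5% (permutation, adjusted p = 0.0006, 0.0004 and 0.0004). Recovery on V was 54.9% and on X 56.1%, and neither passed the threshold against its expectation, which also includes peaks on I (permutation, adjusted p = 0.33 and 0.17). The strongest replicate 2 peak without a replicate 1 peak was I:5310889-5312355, with q = 5.5e-20. At shared peaks the median log2 ratio of -log10 q, replicate 1 over replicate 2, was -1.05 on I (95% bootstrap interval -1.1 to -1.01) and between -0.72 and -0.62 on the other chromosomes. This comparison was chosen after the data were seen.

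**Figure D3:**
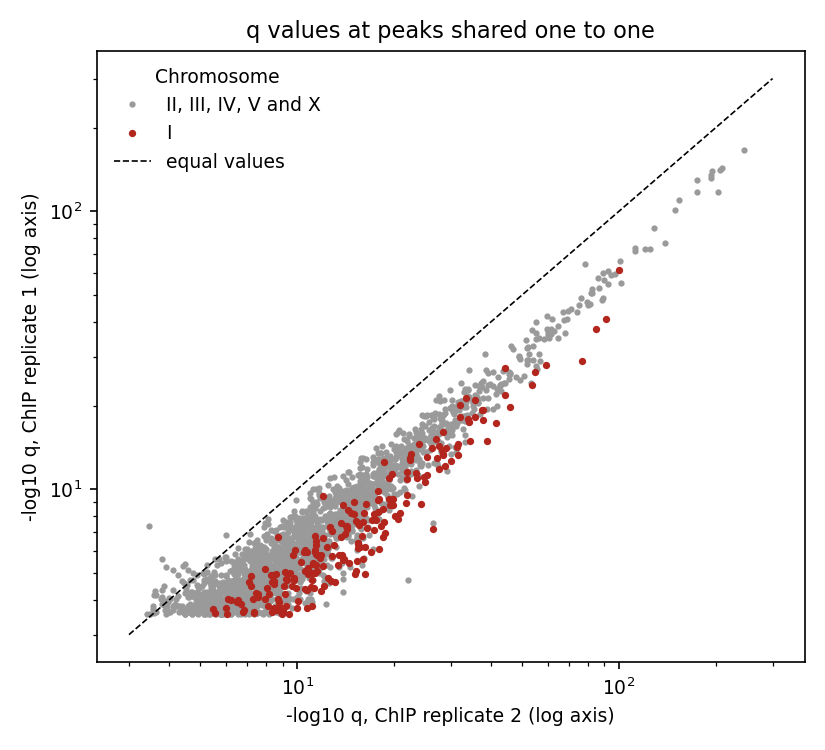
The -log10 q of 2283 peaks shared one to one, replicate 2 on the horizontal and replicate 1 on the vertical axis, both on log scales, with peaks on chromosome I in red and all others in grey. Most points lie below the dashed line of equal values, and those of I lie lower, with a median log2 ratio of -1.05 against -0.68 elsewhere.

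The strongest replicate 1 peak had no counterpart in the other lists. It spanned V:6220803-6230031, 9229 bp, with q = 7.1e-246, and no peak of replicate 2 or of the combined list lay inside it. The region was not isolated. Its flanks of 20 kb held 14 peaks in the replicate 2 list, 14 in the combined list and 7 in replicate 1. In the replicate 2 and combined lists the downstream neighbour lay 747 bp away. The next widest replicate 1 peak measured 4108 bp. Whether the region was bound by JUN-1 was not tested. The peak was 1 of 13 replicate 1 peaks without a replicate 2 peak, and 9 of these 13 were on V. The second of them by rank, II:9133430-9133649, had q = 1.3e-05.

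The combined list was compared with both replicates to see what each contributed. Of its 4277 peaks, 2323 overlapped a peak of both replicates, or 54.3% (95% exact interval 52.8 to 55.8), 1928 a peak of replicate 2 alone, 1 a peak of replicate 1 alone and 25 neither. In the stronger part of the combined list, its top 50% by q, 90.6% overlapped both. The combined list was close to a copy of the replicate 2 list. In 3574 combined peaks, or 83.6% (82.4 to 84.7), start, end and q were equal to those of a replicate 2 peak, while this held for 0 peaks of replicate 1. Values of the combined list and of replicate 2 were thus not independent of each other.

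The 703 combined peaks that differed from replicate 2 lay in 15 of 102 windows of 1 Mb, and in the other 87 windows every peak was identical. Random reassignment of the differing peaks left 1.19 windows untouched on average and at most 7 (permutation p = 0.0002, the smallest possible). Of the differing peaks 367 were on V and 167 on X. The windows included V:11000001-12000000 with 1 identical peak of 107, V:13000001-14000000 with 0 of 100, V:5000001-6000000 with 0 of 78 and IV:11000001-12000000 with 0 of 47. This comparison was chosen after the data were seen.

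**Figure D4:**
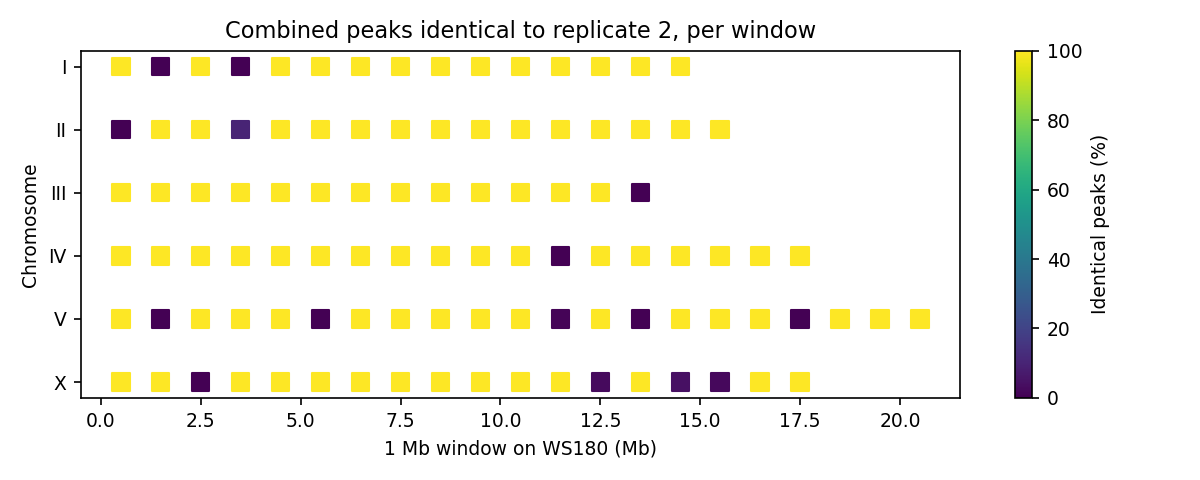
Percentage of combined peaks with the start, end and q of a replicate 2 peak, as colour, in each window of 1 Mb along the 6 chromosomes, at WS180 positions in Mb. In 87 of 102 windows all peaks were identical, and in the other 15 at most 10.0% were.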

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

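Of 41 alternatives to 9 results, 18 were planned before the data were examined and the others were chosen afterwards. For X the list choices were planned, and the test against covered length was not. In 35 the direction and the side of the threshold were kept, or the value stayed within its interval, and none reversed a direction. The alternatives chosen afterwards were all those for chromosome V, for X among the 25 strongest peaks, for recovery on chromosome I and for identity with replicate 2, the clusters, the width limit of 50 bp, and those leaving out a chromosome or the strongest pairs.

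The share of combined peaks found in both replicates moved from 54.3% to 51.3% with a reciprocal overlap of 50%, to 52% with midpoints within 200 bp and to 90.6% in the top 50% of the list, where weak peaks are left out by construction. The share of peaks on X passed the threshold at 18.8% when peaks closer than 5000 bp were counted as 1 cluster (exact binomial p = 0.033), and the cause was not tested. Identity with replicate 2 rose from 83.6% to 91.3% when only q had to be equal and to 91.8% when edges within 10 bp were accepted, since both definitions are looser by construction. The overlap of replicates, 99.5%, was 89% with both lists truncated to 50% of the shorter one, and the call was kept there and with a circular shift of the list. Calls were also kept with the central 33.3% of each autosome as its centre, with 5 or 20 strata of q for chromosome I, and with the 50 or 100 strongest peaks for X. In the list of a single replicate, with no peaks called anew, X held 18.1% to 18.6% of peaks and autosome centres 60.8% to 61.7%. The values of the replicate 2 list were close to fixed in advance, since the combined list nearly repeats it. They are no separate support, although they count among the alternatives that were kept.

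No paired analysis was possible because the inputs, which share replicate numbers with the ChIP libraries, have no list used here. The placement among promoter windows, a second value column and all alternatives of the 5 planned results that need a genome of the build were not run. Depth is unknown, so a peak missing from replicate 1 may be a peak below its detection limit, as the rise to 90.6% among stronger peaks would allow.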

Other observations

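All tests below were chosen after the pattern they measure had been seen at least in part.

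Peaks on chromosome V were narrower as well as denser. At equal q rank, combined peaks on V were 0.63 times as wide as peaks elsewhere (permutation p = 0.0002, adjusted p = 0.00022 over 12 tests), and in replicate 1 the ratio was 0.73 (permutation p = 0.0002, adjusted p = 0.00022). Without matching for rank, median width was 282 bp on V and 382 bp elsewhere in the combined list, and 295 bp and 387 bp in replicate 1. Of 58 combined peaks under 50 bp, 45 were on V, while replicate 1 had 0 such peaks. Taken over all chromosomes, neighbouring peaks lay close together. Their median distance in the combined list was 10741 bp, against 15175 bp when peaks were placed at random (permutation p = 0.0002, the smallest possible). Uneven density along the chromosomes can also shorten this distance, so clustering at a smaller scale was not shown. The widest combined peak was II:10541925-10550428, 8504 bp, and a replicate 1 peak of 3660 bp lay at II:10546198-10549857.

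Fewer replicate 2 peaks on chromosome I were found again in replicate 1. Lower depth or weaker enrichment of replicate 1 as a whole would lower all chromosomes alike, and the median log2 ratio of -log10 q on I minus that on the others was -0.37 (95% bootstrap interval -0.42 to -0.33), which argues against it as the whole cause. The shift covered the entire chromosome: the highest of 5 windows of 3 Mb on I had a median of -1.02, below the lowest of the windows elsewhere with 20 or more pairs, -0.77. A scaling step applied to chromosome I as a unit, in either replicate, is therefore a candidate explanation. The ratio does not show in which of the 2 lists the values on I had shifted. No source used here records such a step, and no biological explanation was tested, since the design compares no conditions.

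The combined list repeats most of replicate 2. Calling the combined list on the reads of both replicates, and replicate 2 on its own reads alone, should change nearly every q, yet 83.6% of peaks were identical. The 87 windows without a differing peak, against at most 7 by chance, are consistent with a threshold set anew in segments of 1 Mb on the same reads, as a hypothesis. Which reads these were stays open. If both lists were called on the reads of both replicates together, the strongest replicate 1 peak should reappear, and 0 peaks of either list lay inside it, but a single region and 13 unmatched replicate 1 peaks in all, 1 of them in the combined list, are too few to decide. Under that explanation the 99.5% overlap between the replicate lists, and the correlations at their shared peaks, could come in part from shared reads.

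The strongest peaks lay on X. A scaling step that raises -log10 q over all of X by 1 factor would act alike at all strengths. The log2 ratio of X to the autosomes was 1.24 at a density of 1 peak per Mb and 0.16 at 10 peaks per Mb, a difference of 1.09 (95% bootstrap interval 0.62 to 1.77). The level of 1 peak per Mb holds the strongest peaks, in which the pattern was first seen. The difference therefore restates the pattern and cannot decide on a single factor. The matching ratio also changed on V, from 0.09 to 0.57, and less on I, II, III and IV. The hypothesis of discrete sites spread evenly along X stays open: the gaps between the 25 strongest X peaks had a coefficient of variation of 0.80, against a median of 0.94 in random draws of 25 X peaks (permutation p = 0.31, adjusted p = 0.53 over 6 chromosomes). The value was not particular to X, since chromosome IV gave 0.81 against 0.97 (permutation p = 0.27, adjusted p = 0.53). Sites that recruit the dosage compensation complex, which acts on X in hermaphrodites, may underlie these peaks, but this is a hypothesis whose sites were not used here and which was not tested. Antibody background was not tested, since a precipitation from worms without the tag was not analysed here, so binding by JUN-1 and enrichment without it cannot be told apart at these peaks.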
